A study of Rattus norvegicus with 22 samples.

How the data were processed

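Rat spinal cord at thoracic level 10 was profiled on Affymetrix rat genome arrays, 1 array per sample. Per the labels the contusion was made with a 10 g rod dropped from 25 mm, and cord was collected 24 h later after perfusion with buffer, stored in RNAlater and extracted with a lipid tissue kit before biotin labelling. Clenbuterol (150 mg/kg), X-rays (10 Gy) and tempol (275 mg/kg) were given 20 min after the injury, and BSO (150 mg/kg) 24 h before it. The labelled clenbuterol dose is very high for this drug, and whether its unit is right is not given in the sources used here. The labels give 3 normal, 3 laminectomy, 2 contusion, 2 clenbuterol, 3 X-ray, 3 tempol, 3 BSO and 3 tempol plus BSO arrays. Whether each array stands for a separate animal is not given in the sources used here, so the p-values measure the spread between these samples.

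The deposited value of each probe set is a signal intensity on a linear scale, with 1 decimal. The submitters' notes name RMA, but the values are neither logarithmic nor quantile normalized. Each array has the same mean, 250.0, once 2% of its values are trimmed at each end, and the signals run from 0.3 to 154527.2. The plan made before the data were examined foresaw a log2 transform for this case, and it was applied. Of the 31099 probe sets 57 are controls and were left out of the tests, with the only 2 empty cells among the controls. Of the 31042 tested, 20826 carry 1 gene symbol, 436 several and 9780 none, and 20764 were matched to the reference tables by Entrez number. All 22 arrays were used.

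The statistics were computed in R 4.3.3 with limma 3.58.1. All arrays entered 1 fit with 8 group means, moderated by eBayes (14 residual and 4.713 prior degrees of freedom), so that groups of 2 and 3 arrays share 1 estimate of the spread. The lone sample left in a group of 2 by a leave-one-out fit is assumed to vary like the other groups. The p-values are two-sided and adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. The median moderated standard deviation was 0.829. Values after ± are standard errors, whose median was 0.677 for 3 arrays against 3, 0.757 for 3 against 2, 0.829 for 2 against 2 and 1.01 for the interaction. A moderated F test covered the 5 treated groups against contusion.

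A total of 33 gene lists of cell types and processes, with 615 genes in all, was written before the data were examined. In them 537 genes were measured, 11 through a synonym. Each gene was represented by its probe set with the highest mean, which left 14217 genes. The lists were tested with camera at a preset correlation of 0.01, adjusted over all lists within a comparison, and with an estimated correlation and fry beside it. The report calls a list shifted on the preset correlation and says where the estimated one ended the call. Lists share some genes. Which genes to name was also fixed beforehand, as those past the threshold with arrays that do not overlap, the smallest p-values where fewer than 5 passed, members of the lists with the smallest p-values, and a set of glutathione, stress, damage and glial genes. In the comparisons chosen later, genes were picked from the tables after the data were seen.

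The alternatives chosen at the outset were quantile normalization, a filter on low signal, eBayes with trend and robust settings, a fit of only the compared groups, array weights, replicate numbers as blocks, leaving out each array, the mean of all probe sets of a gene, and normal cord or the mean of both uninjured groups as the reference for contusion. After the data were seen these were joined by the logarithm of signal plus 32, a hybridization spike covariate, a fit without laminectomy 2 and normal 1, and the comparisons of all contused with all uninjured arrays, of contusion with normal cord and of clenbuterol, X-ray and tempol with each other. In the comparison of all contused with all uninjured arrays each of the 6 contused and 2 uninjured group means has the same weight.

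The fit was tested on simulated data with 200 changed probe sets and 5 simulations per comparison. In laminectomy minus normal it recovered 12.0% of changes of 2 on the log2 scale and 83.5% of changes of 4, with 20 of 508 calls false. For the interaction 26.5% of changes of 4 were recovered. In list simulations of 3 comparisons, the chosen list was called in 0 of 20 simulations where it was not shifted, and the unshifted lists beside it in at most 2 of 640 tests. Every gene was drawn independently there, so these simulations do not show how often lists whose genes vary together are falsely called.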

Results

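The series holds 22 Affymetrix arrays of rat spinal cord at thoracic level 10. There are 3 arrays of normal cord, 3 of cord after laminectomy, 2 of contused cord and 14 of contused cord from treated rats, with 2 arrays for clenbuterol and 3 each for X-ray, tempol, buthionine sulfoximine (BSO) and tempol plus BSO, and the injured cord was taken 24 h after the contusion. The deposited intensity was read for 31042 probe sets and compared on the log2 scale. Laminectomy 2 and normal 1 stood apart from the rest, with median correlations to the other arrays of 0.667 and 0.685 against 0.725 to 0.785 elsewhere, and with the strongest hybridization spikes (14.18 and 13.23 against 10.90 to 13.01). Normal 1 also had the highest log2 RNA end ratio for GAPDH (1.49), and laminectomy 2 the highest for actin (1.38). No difference in RNA end ratios or spikes passed between the 16 contused and 6 uninjured arrays (permutation p of 0.0995 for GAPDH, 0.478 for actin, 0.680 for hexokinase and 0.231 for the spikes). With so few uninjured arrays this does not show that they were alike. The mean GAPDH ratio was 0.37 in contused and 0.64 in uninjured arrays.

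After laminectomy without contusion, 2 genes stood higher than in normal cord. They were Timp1, the inhibitor of matrix metalloproteinases, and Hspb1, the small heat shock protein of stressed astrocytes and neurons. Around them the genes of reactive astrocytes and of matrix remodelling stood higher as groups, together with macrophage markers and with genes of the cell cycle. The neuron markers stood slightly lower as a group, which did not hold with an estimated correlation between the genes (adjusted p = 0.271). Laminectomized cord may thus not be a neutral background for the contusion, although regrouping these arrays could not exclude chance. Whether the normal arrays were processed together with the others is not given in the sources used here.

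Timp1 rose by 5.41 ± 0.62 on the log2 scale (42.6-fold, adjusted p = 0.00174), with all 3 laminectomy arrays above all 3 normal arrays. Hspb1 rose by 3.35 ± 0.49 (10.2-fold, adjusted p = 0.0245), again without overlap of the arrays. These were the only 2 probe sets past the threshold, with 1736 at unadjusted p under 0.05. The count was 5 without normal 1 and 1 without normal 2. Over the alternatives the adjusted p of Timp1 ran from 6.86e-05 to 0.382, the highest with variance estimated from these arrays only, and it reached 0.0300 at most with a single array left out. Hspb1 failed without laminectomy 1 (adjusted p = 0.0895), laminectomy 2 (0.128), normal 2 (0.127) or normal 3 (0.0691), and with the variance estimated from these arrays only. Other genes had small p without passing. The lysosomal glycoprotein gene Gpnmb (2.86 ± 0.48) and the calcium-binding S100a4 (2.89 ± 0.50) both had adjusted p = 0.0572, Lbp, whose product hands bacterial lipid to its receptor, differed by 2.41 ± 0.42 (adjusted p = 0.0592), and the galectin gene Lgals3 by 3.11 ± 0.58 (adjusted p = 0.102).

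The reactive astrocyte genes shifted upward (median 1.16, 14 of 16 higher, adjusted p = 4.21e-11). Of them 7 passed when p was adjusted over the list alone and 2, Timp1 and Hspb1, over all genes. The intermediate filament gene Gfap, the classic mark of astrocyte reaction, differed by 1.46 ± 0.38 without passing over all genes. The matrix remodelling genes, which share Timp1, were also higher (median 0.81, 17 of 22, adjusted p = 1.77e-06, with 4 passing over the list alone and 1 over all genes). Among them were the adhesive phosphoprotein gene Spp1 (1.47 ± 0.41), the collagen cross-linking enzyme gene Lox (1.50 ± 0.50) and the protease gene Adamts1 (1.36 ± 0.43), and without normal 1 the median was 0.38. The macrophage markers followed (median 0.69, 11 of 15, adjusted p = 5.75e-05, with 5 over the list alone and 0 over all genes by limma), including Gpnmb, Spp1 and the lysozyme gene Lyz2 (1.25 ± 0.37). Their median was 0.45 without laminectomy 3.

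Genes of the cell cycle were higher too (median 0.48, 24 of 29, adjusted p = 0.000110), with 0.88 without laminectomy 2 and 0.74 without normal 2. Ube2c, which drives exit from mitosis, differed by 2.82 ± 0.93, the replication clamp gene Pcna by 1.97 ± 0.65 and the mitotic kinase gene Cdk1 by 1.86 ± 0.62, with Pcna at 1.18 without normal 3 and Cdk1 at 0.89 without normal 1. For these 4 lists the shift held when the correlation between the genes was estimated from the data (adjusted p of 0.000699 for reactive astrocytes and for matrix, 0.0106 for macrophages and 0.00245 for the cell cycle).

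The remaining shifts after laminectomy were weaker. Neutrophil markers such as the calprotectin gene S100a9 (1.62 ± 0.68, 0.74 without normal 2) were all higher (median 1.08, 7 of 7, adjusted p = 0.0164, adjusted p = 0.0619 with an estimated correlation), with 0.69 without normal 3. That shift failed without laminectomy 1 (adjusted p = 0.113), laminectomy 3 (0.0663) or normal 1 (0.266), and without both arrays that stand apart (adjusted p = 0.140). Cytokines and chemokines were higher in 15 of 24 (median 0.42, adjusted p = 0.0447, adjusted p = 0.0879 with an estimated correlation, 1 passing over the list alone). The monocyte attractant gene Ccl2 led them (2.93 ± 0.62, adjusted p = 0.220). Their shift failed without laminectomy 1 (adjusted p = 0.113), laminectomy 2 (0.125), laminectomy 3 (0.0663), normal 1 (median 0.25, adjusted p = 0.266) or normal 3 (0.0904), and in all 12 of 13 alternatives ended it, with adjusted p from 0.0528 with replicate numbers as blocks to 0.406 without both arrays that stand apart. The heat shock genes other than Hspb1 moved little, with the chaperonin gene Hspe1 at 0.77 ± 0.44. Their list (median 0.39, 10 of 12, adjusted p = 0.0115, adjusted p = 0.271 with an estimated correlation, 1 over the list alone and 1 over all genes) failed without laminectomy 2 (0.25, adjusted p = 0.312) or normal 3 (0.21, adjusted p = 0.140) and without both arrays that stand apart (adjusted p = 0.0983), and stood at 0.64 without normal 1. Neuron markers, among them the gene Slc32a1 for the transporter that loads inhibitory transmitters into vesicles (−1.29 ± 0.55), were lower in 21 of 23 (median −0.37, adjusted p = 0.0164, adjusted p = 0.271 with an estimated correlation). Without laminectomy 1 (adjusted p = 0.177), laminectomy 3 (−0.23, adjusted p = 0.158) or normal 1 (−0.20, adjusted p = 0.145) that list failed, as it did with the mean of all probe sets of a gene (0.0602).

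Contused cord stood apart from laminectomized cord in groups of genes tied to inflammation and to red cells. The labels give no time of collection for the laminectomy arrays, so the contusion and a difference in time cannot be told apart. Whether blood left in the tissue raised the red cell genes was not tested. Macrophage markers, chemokines and the genes of red cells stood higher in contused than in laminectomized cord. Genes of oligodendrocytes and myelin, of neurons, of astrocytes and of cholesterol synthesis stood lower as groups. None of these losses held with an estimated correlation (adjusted p of 0.0559, 0.0559, 0.177 and 0.266). The general reactive astrocyte genes showed no further shift from laminectomy.

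Among the macrophage markers (median 0.79, 13 of 15 higher, adjusted p = 3.88e-06), Arg1, the arginase gene of alternatively activated cells, was 2.59 ± 0.52 higher. The hemoglobin scavenger receptor gene Cd163 followed at 2.33 ± 1.01 and the inhibitory antibody receptor gene Fcgr2b at 2.21 ± 0.90 (0.89 without laminectomy 1). Among the cytokines and chemokines (median 0.68, 17 of 24, adjusted p = 0.00103) the monocyte attractants Ccl2 (3.02 ± 0.70) and Ccl7 (1.85 ± 0.54) and the neutrophil attractant Cxcl1 (2.45 ± 0.88) differed most. Without laminectomy 2 that median was 0.39. All 6 erythroid genes were higher (median 1.11, adjusted p = 0.000778), with the globin gene Hbb at 2.64 ± 0.65 and the red cell anion exchanger gene Slc4a1 at 2.29 ± 1.08. Over the list alone 1 macrophage, 2 inflammatory and 1 erythroid gene passed, over all genes 0 by limma. With an estimated correlation each of these 3 shifts held (adjusted p = 0.0161). Hmox1, which breaks down heme, was 1.88 ± 0.45 higher. The neutrophil markers were all higher without passing (median 0.76, 7 of 7, adjusted p = 0.0657).

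All 18 oligodendrocyte and myelin genes were lower (median −0.72, adjusted p = 7.27e-07, adjusted p = 0.0559 with an estimated correlation, 1 passing over the list alone). They included Omg, the myelin glycoprotein that restrains axon growth (−2.56 ± 0.65), the raft protein gene Mal (−1.39 ± 0.53) and Ugt8, which makes the myelin galactolipids (−1.16 ± 0.40). A second, much weaker probe set of Ugt8 differed in the opposite direction (1.08). Neuron markers were lower in 19 of 23 (median −0.68, adjusted p = 1.11e-06, adjusted p = 0.0559 with an estimated correlation, 3 passing over the list alone), and the median was −0.43 without contusion 1. The axonal neurofilament genes Nefl (−2.07 ± 0.56) and Nefh (−2.09 ± 0.62) and the gene of the synaptic fusion protein Snap25 (−1.71 ± 0.62) showed it, with Nefh at −1.21 and Snap25 at −0.79 without contusion 1 and Snap25 at −2.64 without contusion 2. Astrocyte markers were lower in 12 of 14 (median −0.72, adjusted p = 0.000156, adjusted p = 0.177 with an estimated correlation, 3 passing over the list alone), with Gfap at −1.40 ± 0.42, the water channel gene Aqp4 at −1.55 ± 0.49 and the bicarbonate transporter gene Slc4a4 at −1.41 ± 0.49. Against normal cord Gfap in contused cord differed by only 0.05 ± 0.42. Cholesterol synthesis was lower in 17 of 19 (median −0.51, adjusted p = 0.00332, adjusted p = 0.266 with an estimated correlation), with Fdps, an enzyme of the sterol pathway, at −1.90 ± 0.65 and the sterol sensor gene Insig1 at −2.55 ± 0.96. Insig1 was −1.42 without contusion 1 and Fdps −1.14 without contusion 2. That list failed without laminectomy 2 (−0.38, adjusted p = 0.105) or contusion 1 (−0.24, adjusted p = 0.0969), with the spike covariate (adjusted p = 0.0755) and without both arrays that stand apart (0.0985).

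The reactive astrocyte genes did not differ (median 0.06, mean −0.07, adjusted p = 0.552), and Timp1 was 0.74 ± 0.70 higher. Targets of the oxidative stress factor NRF2 (median 0.23, adjusted p = 0.108), the glutathione genes (−0.13, adjusted p = 0.823) and the microglia markers (0.10, adjusted p = 0.823) did not shift either. Gene by gene, the only probe set past the threshold is one that the annotation used here does not name, which fell by 3.96 ± 0.51 (adjusted p = 0.00931). Its signals were 21.3 and 15.3 in the contusion arrays and between 63.9 and 415.5 in all others. By chance 1552.1 probe sets would lie at unadjusted p under 0.05, and 1669 did. It failed without contusion 1 (adjusted p = 0.0904) or contusion 2 (0.135). The count past the threshold was 3 without laminectomy 1, and 0 without both arrays that stand apart, with the logarithm of signal plus 32 or with the variance estimated from these arrays only.

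Against normal cord, in a comparison added after the data were seen, contused cord had 15 probe sets past the threshold, 14 higher and 1 lower, among them genes of inflammation and of heme breakdown. Timp1 (6.15 ± 0.70) and Ccl2 (5.96 ± 0.70) both rose (adjusted p = 0.00104) with both contusion arrays above all 3 normal arrays. No single array left out ended these calls (adjusted p up to 0.0484), but with the variance estimated from these arrays only they failed (0.596 and 0.518), and 0 probe sets passed by limma. The macrophage chemokine gene Ccl6 rose by 4.81 ± 0.62 (adjusted p = 0.00203, 0.109 without contusion 2). Slpi, an inhibitor of neutrophil elastase, rose by 4.12 ± 0.55 (adjusted p = 0.00295, 0.0658 without contusion 1, 0.116 without contusion 2). Gpnmb rose by 4.01 ± 0.54 (adjusted p = 0.00295, 0.173 without contusion 1) and Hmox1 by 3.05 ± 0.45 (adjusted p = 0.00850, 0.173 without contusion 1, 0.123 without contusion 2). Ccl7 rose by 3.31 ± 0.54 (adjusted p = 0.0243, 0.223 without contusion 1, 0.158 without contusion 2, 0.0854 without normal 3). Tnfaip6, a secreted hyaluronan-binding brake on inflammation, rose by 2.72 ± 0.47 (adjusted p = 0.0390, 0.223 without contusion 1, 0.240 without contusion 2, 0.0725 without normal 1, 0.149 without normal 3). Every one of these genes was higher in both contusion arrays than in any normal array. The count was 5 without contusion 1 and 4 without contusion 2.

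As groups, the macrophage markers (median 1.64, adjusted p = 2.33e-13), the cytokines and chemokines (1.13, adjusted p = 3.65e-06), the matrix genes (0.90, adjusted p = 4.35e-07) and the reactive astrocyte genes (0.87, adjusted p = 3.65e-06) were higher than in normal cord. Without contusion 2 the inflammatory median was 0.70. Neuron markers (−1.05, adjusted p = 1.73e-11) and oligodendrocyte and myelin genes (−0.81, adjusted p = 2.41e-08) were lower. These 6 held with an estimated correlation, with 0.0203 for the myelin genes as the highest adjusted p, and so did the neutrophil markers (1.61, adjusted p = 6.20e-05, 2.42 without contusion 1) and the erythroid genes (1.02, adjusted p = 0.00183). Astrocyte markers (−0.80, adjusted p = 7.67e-05, adjusted p = 0.0882 with an estimated correlation) and cholesterol synthesis (−0.58, adjusted p = 0.000464, adjusted p = 0.113 with an estimated correlation) were lower. The unfolded protein response was higher (0.45, adjusted p = 0.0232, adjusted p = 0.0694 with an estimated correlation), though not without contusion 1 (0.192) or normal 2 (0.0645). NRF2 targets (0.35, adjusted p = 0.0103) failed without contusion 1 (0.0736) and stood at 0.54 without contusion 2. Cell cycle genes (0.50, adjusted p = 0.00790) failed without contusion 1 (0.107) and stood at 0.77 without contusion 2 and 0.32 without normal 1. Immediate early genes of the cyclic AMP response (0.26, adjusted p = 0.0205) failed without contusion 1 (0.0770) or normal 2 (0.0665) and stood at 0.42 without contusion 2. The channels (−0.53, adjusted p = 0.0200) failed without contusion 1 (−0.38, adjusted p = 0.0736) or normal 2 (−0.32, adjusted p = 0.0645) and stood at −0.32 without contusion 2.

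Taking all 16 contused arrays against the 6 uninjured ones, a comparison chosen after the data were seen that mixes injury with treatment, gave the fullest picture of the lesion. Monocyte and neutrophil attractants, red cell genes and heme breakdown rose. Some genes of synapses, axons and myelin fell. Here 99 probe sets passed the threshold, 66 higher and 33 lower, and the count was 63 without laminectomy 3, 59 without contusion 1 and 61 without X-ray 2. The lower probe sets depended on single arrays far more than the higher ones. Without the pair of arrays that stand apart 76 higher and 3 lower passed. The lower count was 9 without normal 1, 17 without normal 2, 15 without normal 3, 10 without laminectomy 2 and 10 without laminectomy 3. It was 12 without contusion 1, 20 without clenbuterol 1, 17, 16 and 19 without X-ray 1, 2 and 3, 19 without tempol 1 and 21 without tempol plus BSO 3.

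Ccl2 rose by 4.49 ± 0.37 (adjusted p = 6.75e-06), Slpi by 3.13 ± 0.29 (adjusted p = 3.07e-05), Hbb by 2.99 ± 0.34 (adjusted p = 0.000166), Ccl7 by 2.71 ± 0.28 (adjusted p = 6.81e-05) and Hmox1 by 2.33 ± 0.24 (adjusted p = 5.69e-05). The neutrophil attractant Cxcl2 rose by 2.98 ± 0.40 (adjusted p = 0.00136), S100a9 by 2.70 ± 0.40 (adjusted p = 0.00328), the macrophage chemokine gene Ccl3 by 2.22 ± 0.37 (adjusted p = 0.00836), Arg1 by 1.82 ± 0.28 (adjusted p = 0.00427) and the lipid droplet gene Plin2 by 1.37 ± 0.22 (adjusted p = 0.00585). In every one of these genes all 16 contused arrays stood above all 6 uninjured arrays. Timp1 (3.25 ± 0.37, adjusted p = 0.000166), Gpnmb (1.82 ± 0.29) and the immediate early gene Egr1 (2.47 ± 0.43, adjusted p = 0.0122) rose with overlapping arrays. The cytokine gene Il1b differed by 1.81 ± 0.42 without passing (adjusted p = 0.0878). Leaving out any one array ended none of these calls.

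Omg fell by 2.18 ± 0.34 (adjusted p = 0.00585) and Ugt8 by 1.39 ± 0.21 (adjusted p = 0.00427), both with overlapping arrays, although the mean of both Ugt8 probe sets differed by only −0.49 (adjusted p = 0.529). Cplx1, which clamps synaptic vesicle fusion, fell by 1.77 ± 0.28 (adjusted p = 0.00585) and the oligodendrocyte receptor gene Gpr37 by 1.57 ± 0.27, with all 16 contused arrays below all 6 uninjured arrays. Without laminectomy 2 and normal 1 together the adjusted p of these last 2 was 0.0536 and 0.0668. Further losses passed narrowly. Nefl fell by 1.49 ± 0.29 (adjusted p = 0.0319, ended in 11 of 22 leave-one-out fits, up to 0.106 without normal 1), and the sodium channel gene Scn1a by 1.59 ± 0.32 (adjusted p = 0.0361, ended in 10 of 22, up to 0.105 without laminectomy 2). Aqp4 fell by 1.23 ± 0.26 (adjusted p = 0.0482, ended in 21 of 22, up to 0.143 without laminectomy 2), and its other probe sets differed by 0.04 and 0.08. Over all alternatives the adjusted p of these 3 genes reached 0.213, 0.122 and 0.618. The genes Gclc (0.16 ± 0.29, adjusted p = 0.888) and Gclm (−0.09 ± 0.34, adjusted p = 0.955) of the enzyme that limits glutathione synthesis did not differ.

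Among the lists, the cytokines and chemokines (median 0.69, 19 of 24 higher, adjusted p = 7.84e-12) had 9 genes passing over the list alone and 6 over all genes, the macrophage markers (0.93, 14 of 15, adjusted p = 4.90e-12) 8 and 5. Matrix genes (0.63, 20 of 22, adjusted p = 1.08e-08), neutrophil markers (0.96, 7 of 7, adjusted p = 2.35e-05, 0.50 without normal 1), erythroid genes (0.57, 6 of 6, adjusted p = 0.000171), reactive astrocyte genes (0.66, 14 of 16, adjusted p = 0.000444) and immediate early genes of the cyclic AMP response (0.28, 19 of 24, adjusted p = 0.00342) were higher. Oligodendrocyte and myelin genes (−0.60, 18 of 18 lower, adjusted p = 1.27e-10, with 7 and 3 genes passing) and neuron markers (−0.55, 21 of 23 lower, adjusted p = 2.80e-09, with 9 and 2) were lower. All of these held with an estimated correlation. Astrocyte markers were lower (−0.59, adjusted p = 1.01e-05, adjusted p = 0.0621 with an estimated correlation). Weaker calls were the NRF2 targets (0.20, adjusted p = 0.0320, adjusted p = 0.0641 with an estimated correlation) and the glucocorticoid-responsive genes (0.21, adjusted p = 0.0274, adjusted p = 0.0621 with an estimated correlation). Cholesterol synthesis (−0.30, adjusted p = 0.0310, adjusted p = 0.332 with an estimated correlation) and the voltage-gated and ligand-gated channels (−0.33, adjusted p = 0.0465, adjusted p = 0.0621 with an estimated correlation) were the other two. The NRF2 call failed without laminectomy 1 (adjusted p = 0.0785), laminectomy 3 (0.0778), clenbuterol 1 (0.0580), tempol plus BSO 1 (0.0604) or normal 3 (0.076, adjusted p = 0.0810), and its median was 0.13 without BSO 3. The glucocorticoid call failed without laminectomy 1 (adjusted p = 0.138), clenbuterol 1 (0.0580), normal 2 (0.0684) or normal 3 (0.14, adjusted p = 0.0810), and its median was 0.32 without clenbuterol 2 and 0.39 without normal 1. Cholesterol synthesis failed without laminectomy 2 (−0.17, adjusted p = 0.179), clenbuterol 1 (adjusted p = 0.0580), normal 1 (−0.16, adjusted p = 0.177) or normal 2 (adjusted p = 0.0594), with the mean of all probe sets of a gene (0.217), with the spike covariate (0.183) and without both arrays that stand apart (0.626). The channels failed in 13 of 22 leave-one-out fits, with adjusted p up to 0.106 without normal 2 and a median of −0.21 without normal 1, and without both arrays that stand apart (0.0782). The glutathione genes stayed at 0.02 (adjusted p = 0.891).

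**Figure D1:**
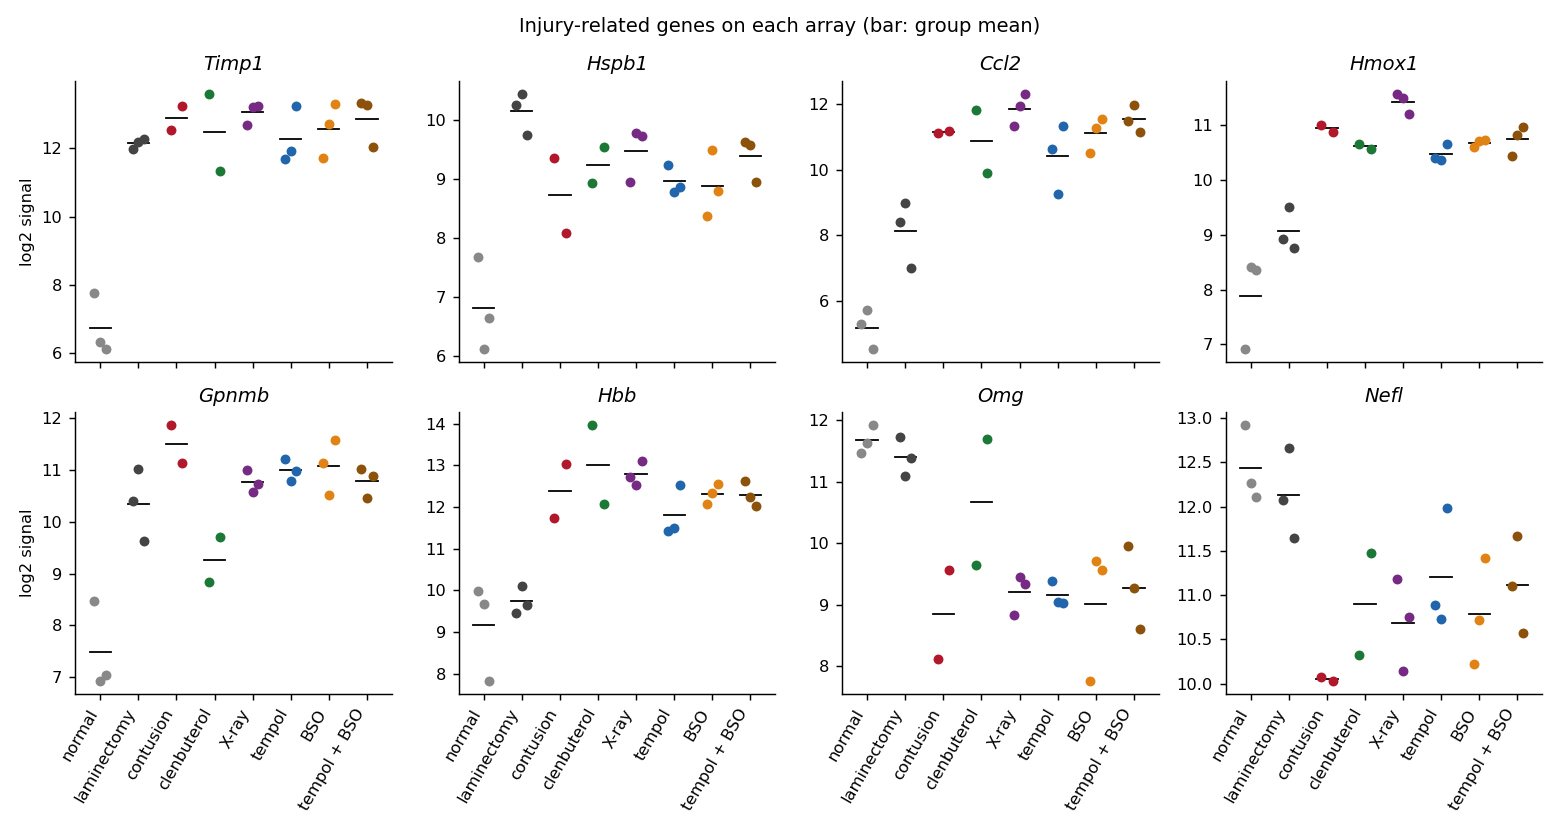
Log2 signal of injury genes in each array by group, with a bar at the group mean. Timp1 and Hspb1 rose after laminectomy by 5.41 and 3.35, and Ccl2 rose by 4.49 in all 16 contused arrays against the 6 uninjured arrays.

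The contusion arrays are shared by all 5 comparisons of a treated group with contusion, so a chance deviation in these 2 arrays enters every one of them. Clenbuterol is an agonist of beta-adrenergic receptors, given 20 min after the injury at 150 mg/kg in the labels, a unit that could not be checked here. More lists were called against contusion for it than for any other treatment, but only the glucocorticoid-responsive genes held with an estimated correlation. Genes that respond to glucocorticoids stood higher. Macrophage markers and cell cycle genes stood lower than in contused cord without treatment, which did not hold with an estimated correlation (adjusted p of 0.0537 and 0.0821). Genes of myelin, astrocytes, neurons and cholesterol synthesis stood higher, and these did not hold either (adjusted p of 0.210, 0.300, 0.311 and 0.210 with an estimated correlation). The same lists stood lower in contusion minus laminectomy, where the same contusion arrays enter with the opposite sign. Chance low values in those arrays would thus give both shifts.

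All 16 glucocorticoid-responsive genes were higher (median 0.89, adjusted p = 0.000122, adjusted p = 0.0149 with an estimated correlation, 1 passing over the list alone and 0 over all genes by limma). The clock gene Per1 (2.41 ± 0.68, adjusted p = 0.683), the kinase phosphatase gene Dusp1 (1.23 ± 0.51), the transcription factor gene Klf9 (0.91 ± 0.44) and Fkbp5, the chaperone partner of the glucocorticoid receptor (0.93 ± 0.49), showed it. None of them passed, and Per1 was 1.35 without clenbuterol 2, Dusp1 0.81 without contusion 2 and Fkbp5 0.49 without contusion 1. No array left out ended this call, and the median was 0.59 without clenbuterol 1. Per1, Dusp1 and similar genes also answer to cyclic AMP. The list of immediate early genes of the cyclic AMP response did not shift (median 0.10, adjusted p = 0.798). Its mean relative to normal cord was 0.66 in contused cord and 0.72 after clenbuterol. The orphan receptor gene Nr4a1 stood at 0.85 ± 0.86 (0.012 without contusion 1, 1.68 without contusion 2, 1.59 without clenbuterol 1, 0.10 without clenbuterol 2). Cord was taken 24 h after the injury, so an earlier, short-lived response could be missed. A cyclic AMP origin of Per1 and Dusp1 thus stays open.

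Macrophage markers were lower in 11 of 15 (median −0.94, adjusted p = 0.000473, adjusted p = 0.0537 with an estimated correlation, 2 passing over the list alone). Gpnmb (−2.23 ± 0.59, adjusted p = 0.674), Spp1 (−1.79 ± 0.50), Arg1 (−1.62 ± 0.57) and the lysosomal membrane gene Cd68 (−2.53 ± 0.96) were lower without passing over all genes. The microglia markers (median 0.09, adjusted p = 0.892) stayed level, as did the cytokines and chemokines (0.26, adjusted p = 0.259), with Ccl2 at −0.28 ± 0.76. Neutrophil markers (−0.58, adjusted p = 0.456) and erythroid genes (−0.10, adjusted p = 0.906) did not pass. Cell cycle genes were lower in 23 of 29 (median −0.47, adjusted p = 0.0271, adjusted p = 0.0821 with an estimated correlation), among them Cks2, a subunit of the mitotic kinase (−2.37 ± 0.83, −3.81 without clenbuterol 1, −0.93 without clenbuterol 2). That list failed without contusion 1 (−0.29, adjusted p = 0.297) or clenbuterol 2 (−0.47, adjusted p = 0.203) and with the spike covariate (adjusted p = 0.0761).

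Oligodendrocyte and myelin genes were higher in 16 of 18 (median 0.50, adjusted p = 0.000350, adjusted p = 0.210 with an estimated correlation), with Omg at 1.82 ± 0.72 (1.10 without contusion 1, 2.84 without clenbuterol 1, 0.80 without clenbuterol 2) and Ugt8 at 1.27 ± 0.44, the second Ugt8 probe set again in the opposite direction (−1.85). Cholesterol synthesis was higher in 17 of 19 (median 0.59, adjusted p = 0.000425, adjusted p = 0.210 with an estimated correlation), with Fdps at 2.08 ± 0.71 and Insig1 at 2.24 ± 1.05, and a median of 0.39 without contusion 1. Insig1 was 1.11 without contusion 1 and 3.38 without contusion 2, and Fdps 1.32 without contusion 2. Astrocyte markers such as Aqp4 (1.49 ± 0.54) were higher in 11 of 14 (median 0.66, adjusted p = 0.00473, adjusted p = 0.300 with an estimated correlation). They failed without contusion 1 (0.42, adjusted p = 0.121) or clenbuterol 1 (0.61, adjusted p = 0.0993). Neuron markers such as Nefh (1.54 ± 0.68, 0.66 without contusion 1, 2.42 without contusion 2) were higher in 17 of 23 (median 0.61, adjusted p = 0.0157, adjusted p = 0.311 with an estimated correlation), and failed without contusion 1 (0.19, adjusted p = 0.528) or clenbuterol 2 (0.30, adjusted p = 0.718) and with the mean of all probe sets of a gene (0.22, adjusted p = 0.210). The only probe set past the threshold was again the unnamed one, higher by 4.28 (adjusted p = 0.0110) because both contusion arrays were low, with 1663 at unadjusted p under 0.05. It failed without contusion 1 (adjusted p = 0.0736), contusion 2 (0.290), clenbuterol 1 (0.0704) or clenbuterol 2 (0.0772), where 1, 0, 1 and 3 other probe sets passed. Of the named genes Dazap1, an RNA-binding protein gene, came closest (−3.35 ± 0.57, adjusted p = 0.186).

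**Figure D2:**
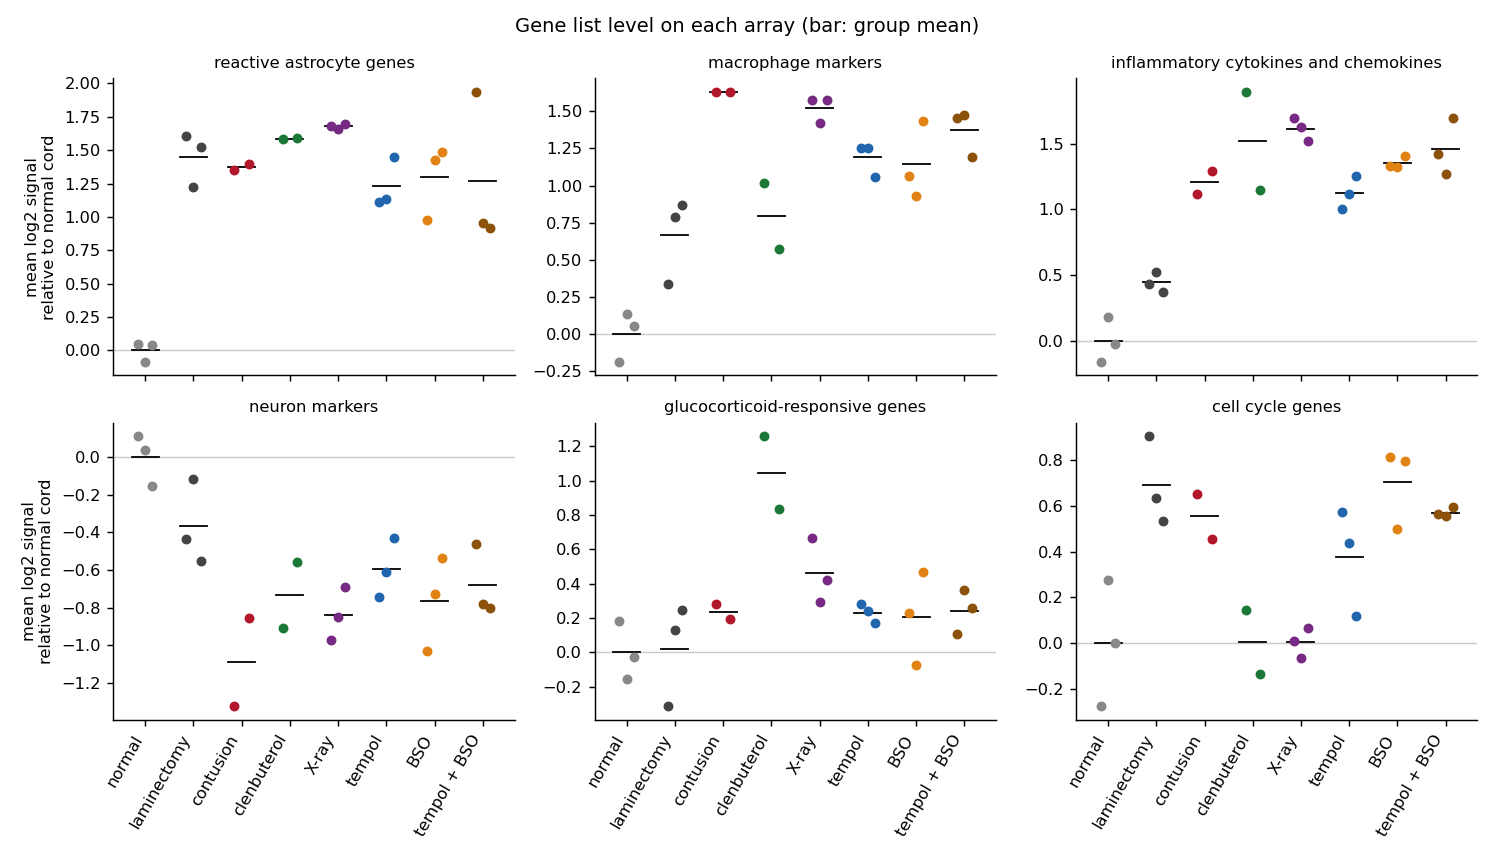
Mean log2 signal of each gene list in each array relative to normal cord, with a bar at the group mean. Glucocorticoid-responsive genes averaged 1.05 after clenbuterol against 0.24 in contused cord, and macrophage markers 0.79 against 1.63.

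Irradiated contused cord, exposed to 10 Gy 20 min after the injury, had lower expression of cell cycle genes, the genes that dividing cells use. Their mean relative to normal cord was 0.0038 after X-ray and 0.0054 after clenbuterol, against 0.55 in untreated contused cord. The lower level was thus not particular to X-ray. Against tempol, whose mean was 0.38, these genes were not called lower after X-ray or after clenbuterol. Those comparisons, chosen after the data were seen, use no contusion arrays. Astrocyte, myelin and cholesterol genes and markers of Schwann cells and nerve roots were higher than in unirradiated contused cord. None of these 4 shifts held with an estimated correlation (adjusted p of 0.371, 0.477, 0.371 and 0.0937). Targets of p53, the factor that halts damaged cells, did not shift as a group, and neither did the macrophage markers.

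Cell cycle genes were lower in 22 of 29 (median −0.65, adjusted p = 0.00478, adjusted p = 0.0251 with an estimated correlation), with the mitotic cyclin gene Ccnb2 at −1.41 ± 0.55 and the replication helicase genes Mcm6 at −2.46 ± 0.97 and Mcm4 at −1.27 ± 0.53. Without contusion 1 that list (−0.64) failed, with adjusted p = 0.155. Among the p53 targets (median 0.13, 11 of 19 higher, adjusted p = 0.326), the cyclin gene Ccng1 was 1.50 ± 0.61 higher, the cell cycle inhibitor gene Cdkn1a 0.81 ± 1.20 and the p53 ligase gene Mdm2 0.24 ± 0.42. Astrocyte markers were higher in 13 of 14 (median 0.58, adjusted p = 0.00478, adjusted p = 0.371 with an estimated correlation), with Aqp4 at 1.20 ± 0.49 and the calcium-binding S100b at 0.91 ± 0.44. Cholesterol synthesis was higher in 17 of 19 (median 0.45, adjusted p = 0.00478, adjusted p = 0.371 with an estimated correlation), with Fdps at 2.24 ± 0.65 and Insig1 at 2.82 ± 0.96 (1.47 for Fdps without contusion 2, 1.68 for Insig1 without contusion 1). Both lists failed without contusion 1 (0.42 and 0.32, each with adjusted p = 0.155), and cholesterol synthesis also without X-ray 1 (0.33, adjusted p = 0.0680).

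Oligodendrocyte and myelin genes were higher in 15 of 18 (median 0.35, adjusted p = 0.0215, adjusted p = 0.477 with an estimated correlation), including Mal (1.15 ± 0.53) and the late myelin gene Ermn (1.70 ± 0.64, 2.92 without contusion 1, 0.48 without contusion 2). They failed without contusion 1 (adjusted p = 0.103), contusion 2 (0.231), X-ray 1 (0.119) or X-ray 2 (0.0822), with quantile normalization (0.0696) and with the spike covariate (0.0782). All 6 Schwann cell and root markers were higher (median 0.74, adjusted p = 0.0107, adjusted p = 0.0937 with an estimated correlation, 1 passing over the list alone), led by Ngfr, the low-affinity neurotrophin receptor gene (2.34 ± 0.68, adjusted p = 0.942). That list failed without contusion 2 (0.50, adjusted p = 0.420) or X-ray 1 (0.46, adjusted p = 0.118) and stood at 1.14 without contusion 1. The cytokines and chemokines (median 0.32, adjusted p = 0.0673), the neuron markers (0.42, adjusted p = 0.0959) and the macrophage markers (−0.01, adjusted p = 0.940) did not pass. By limma 0 probe sets passed and 1492 had unadjusted p under 0.05. The closest named gene was Rd3l (−3.32 ± 0.55, adjusted p = 0.123), and 1 probe set passed without contusion 1 or without X-ray 2.

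Tempol, a nitroxide that imitates superoxide dismutase, gave no shift that held. Neuron markers were called higher than in contused cord, but not with an estimated correlation (adjusted p = 0.297) and not without contusion 1 (0.14). The NRF2 targets and the glutathione genes, where a change in oxidative stress would be read, did not shift. Macrophage markers were lower in median without passing.

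Neuron markers were higher in 21 of 23 (median 0.53, adjusted p = 0.000226, adjusted p = 0.297 with an estimated correlation). The neuronal tubulin gene Tubb3 (0.93 ± 0.44), Nefl (1.14 ± 0.56, 0.75 without tempol 3) and Slc17a6, which encodes a vesicular glutamate transporter (0.86 ± 0.42), were higher, while Gad2, which makes the inhibitory transmitter GABA, was lower (−1.88 ± 0.93). None of them passed over the list alone or over all genes. Without contusion 1 the median was 0.14 (adjusted p = 0.782) and without contusion 2 it was 0.88. Hmox1 (−0.47 ± 0.45), the quinone reductase gene Nqo1 (−0.27 ± 0.42) and Gclm (−0.52 ± 0.65) lay a little lower, with the NRF2 targets at −0.32 (17 of 23 lower, adjusted p = 0.191). Gclm ran from −0.94 without tempol 3 to −0.17 without tempol 1. The glutathione genes stood at −0.03 (adjusted p = 0.778), the genes that remove peroxide and superoxide at −0.08 (adjusted p = 0.913) and the macrophage markers at −0.50 (adjusted p = 0.122). Single genes with small unadjusted p, such as the lysosomal transporter gene Spns1 (−3.06 ± 0.73) and the phospholipid enzyme gene Lpcat4 (3.15 ± 0.76), did not pass. By limma 0 probe sets passed and 875 had unadjusted p under 0.05, fewer than chance would give, and 1 passed without contusion 1 or without tempol 2.

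BSO blocks glutamate-cysteine ligase and so the synthesis of glutathione. In the cord treated with it, no rise of the genes that would rebuild glutathione was called. In simulated data this comparison recovered 10% of changes of 2 on the log2 scale, so a moderate rise could be missed. BSO was given 24 h before the contusion and the cord taken 24 h after it, so an earlier rise could be missed too. No list shifted and no gene passed.

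The ligase subunit genes Gclc (0.20 ± 0.54) and Gclm (−0.35 ± 0.65), the synthetase gene Gss (−0.25 ± 0.65), the reductase gene Gsr (−0.85 ± 0.93) and the cystine transporter gene Slc7a11 (0.01 ± 0.68) all lay within their errors. Gsr was −1.65 without contusion 1, −0.04 without contusion 2 and −0.52 without BSO 3. The glutathione genes stood at a median of −0.04 (adjusted p = 0.980) and the NRF2 targets at −0.18 (adjusted p = 0.416), with Hmox1 at −0.26 ± 0.45. Gsta3, a glutathione transferase gene, differed by −2.96 ± 0.95 without passing. Among the named genes with the smallest p were Rcan1, which restrains calcineurin (−2.32 ± 0.50), and Herpud1, which clears misfolded protein from the endoplasmic reticulum (−2.21 ± 0.51), both with adjusted p = 0.968. Herpud1 was the 1 gene of the unfolded protein response list to pass over the list alone (list median −0.23, adjusted p = 0.416). The immediate early gene Ier2 differed by −3.07 ± 0.82, lower in all 3 BSO arrays, without passing. Macrophage markers (−0.49) and neuron markers (0.47) both had adjusted p = 0.113. In all 0 probe sets passed by limma and 1074 had unadjusted p under 0.05, with 1 passing without contusion 1.

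**Figure D3:**
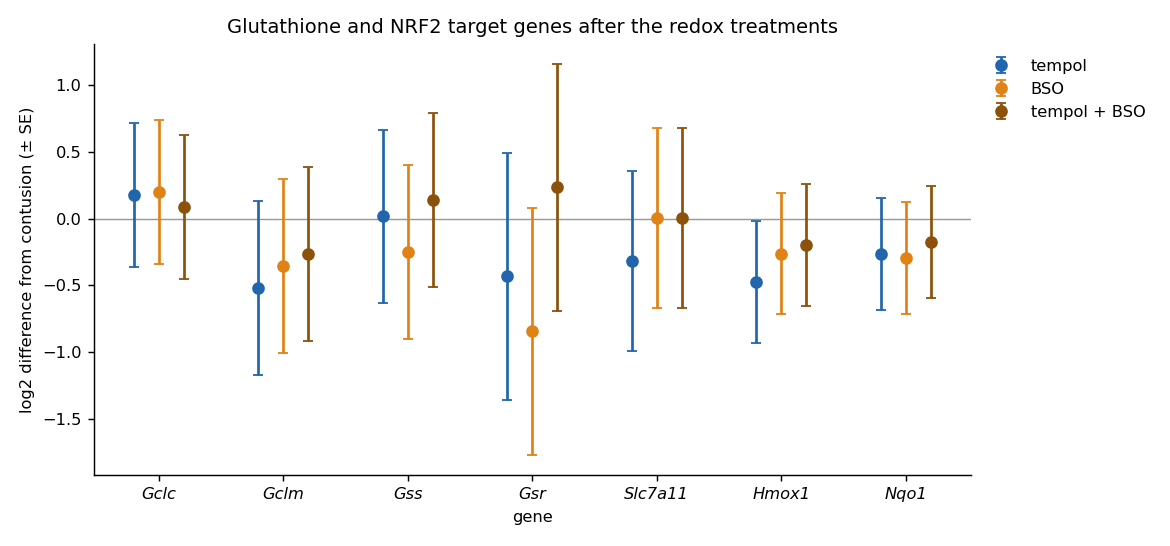
Log2 difference from contusion, with standard errors, of genes of glutathione synthesis and of NRF2 targets after tempol, BSO or both. For BSO, Gclc differed by 0.20 and Gclm by −0.35, neither of them past the threshold.

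After tempol together with BSO only the neuron markers were called higher than in contused cord, and neither with an estimated correlation (adjusted p = 0.968) nor without contusion 1 (0.23) did that hold. No shift of the glutathione genes was called. No gene or list separated the combination from either agent alone.

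Neuron markers were higher in 18 of 23 (median 0.45, adjusted p = 0.0125, adjusted p = 0.968 with an estimated correlation), with Tubb3 at 0.94 ± 0.44 and Nefl at 1.06 ± 0.56, and with Gad2 again lower (−2.53 ± 0.93). The list failed without contusion 1 (0.23, adjusted p = 0.968) or tempol plus BSO 1 (0.45, adjusted p = 0.231) and with the mean of all probe sets of a gene (0.38, adjusted p = 0.304), and stood at 0.76 without contusion 2. Gclc differed by 0.09 ± 0.54 and Gclm by −0.27 ± 0.65, with the glutathione genes at a median of 0.07 although their test pointed down (adjusted p = 0.994). The mechanically gated channel gene Piezo1 (2.01 ± 0.44, adjusted p = 0.924) and the Wnt signal gene Dvl1 (−3.82 ± 0.84, adjusted p = 0.928) were single genes with small unadjusted p. The limma test passed 0 probe sets and 1237 had unadjusted p under 0.05, with 1 passing without contusion 1.

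Against tempol alone, the combination left the neuron markers at 0.01 (adjusted p = 0.766) and the glutathione genes at 0.12 (adjusted p = 0.703), with Gclc at −0.09 ± 0.48 and Gclm at 0.25 ± 0.58. Avil, an actin regulator gene of sensory neurons (3.00 ± 0.66), and the transcription factor gene Sim2 (4.95 ± 1.10) had adjusted p = 0.783. As single genes 0 passed by limma and 1407 probe sets had unadjusted p under 0.05, and 1 passed without tempol 2 or without tempol plus BSO 3. Against BSO alone, Herpud1 was 1.92 ± 0.46 higher (adjusted p = 0.905), the ubiquitin protease gene Usp47 2.72 ± 0.58 (adjusted p = 0.879) and Nefl 0.33 ± 0.50. Here too 0 probe sets passed by limma, with 1283 at unadjusted p under 0.05, and 1 passed without tempol plus BSO 2 or without BSO 3. The interaction, which asks whether tempol acts differently when BSO is present, gave 0 probe sets by limma with 1068 at unadjusted p under 0.05. Herpud1 (3.27 ± 0.68), the ubiquitin ligase gene Rnf180 (−2.93 ± 0.64) and Ngfr (−4.05 ± 0.91) had small unadjusted p for it without passing. Macrophage markers (0.69, adjusted p = 0.171), the unfolded protein response (0.32, adjusted p = 0.221) and the glutathione genes (0.15, adjusted p = 0.898) did not pass.

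Across all 5 treatments together the F test found 0 genes by limma, with 1737 probe sets at unadjusted p under 0.05 and a smallest adjusted p of 0.15. The closest named genes were Dazap1 (adjusted p = 0.190), Herpud1 (0.215), the arginine methyltransferase gene Carm1 (0.237), Rcan1 (0.237), the chromodomain gene Cdyl2 (0.242) and Rd3l (0.248). The count was 1 without contusion 1, clenbuterol 1, clenbuterol 2 or X-ray 2. How small a difference could have been seen was tested on simulated data. A change of 2 on the log2 scale was recovered for 8.5% of probe sets in tempol minus contusion and for 0.5% in clenbuterol minus contusion, against 67.0% in the comparison of all contused with all uninjured arrays. A gene with a moderate change after a treatment could therefore not be expected to pass by itself. A whole list shifted by 1 was called in 20 of 20 simulations, and by 0.5 in 9, 7 and 8 of 20 for contusion, clenbuterol and tempol. The genes were drawn independently there, so these shares may not hold for lists whose genes vary together.

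**Figure D4:**
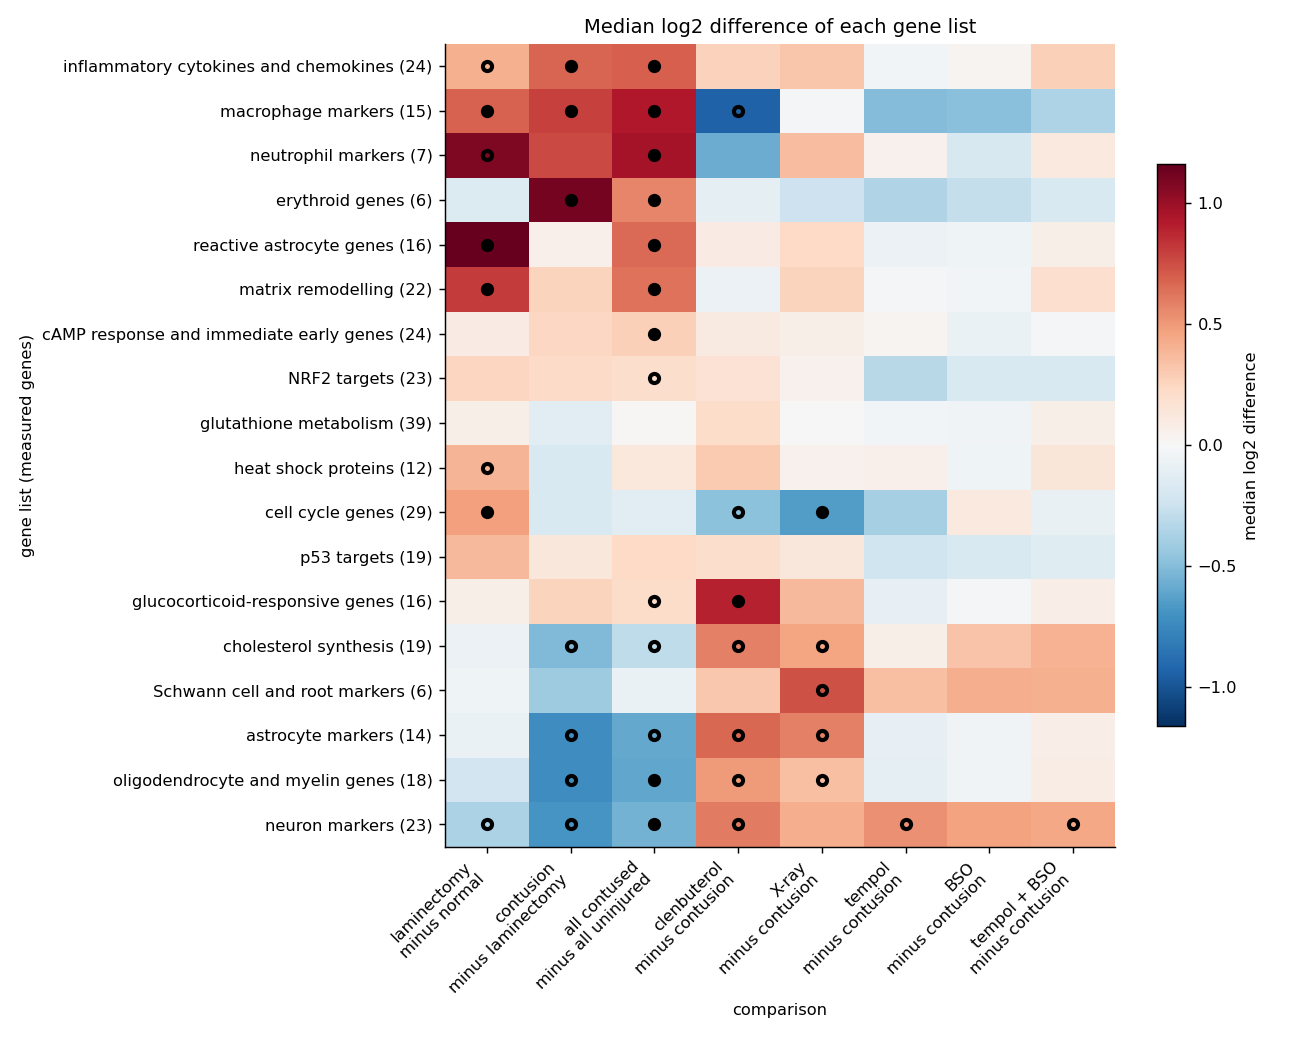
Median log2 difference of 18 gene lists in each comparison, with a filled circle where the called shift held with an estimated correlation and an open circle where it did not. Glucocorticoid-responsive genes after clenbuterol (0.89) and cell cycle genes after X-ray (−0.65) were the only shifts of a treated group from contusion that held with an estimated correlation. The X-ray call was lost without contusion 1.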

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

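Of the 17 counts, 221 of 279 values under an alternative stayed close to the first value and 58 moved. Of the 41 list shifts named, 375 of 471 stayed and 96 became weaker, and of the 164 named gene values 2351 of 2463 stayed, 82 became weaker, 26 stronger and 4 reversed. A change of sign in a gene counted as reversed only if the gene passed in either fit or moved by more than its standard error. Smaller changes of sign counted as stayed. With the filter on low signal, which tests fewer probe sets, laminectomy minus normal gave 9 probe sets instead of 2, and X-ray and BSO against contusion 1 each instead of 0. The trend and robust settings gave 16 for laminectomy minus normal, 34 instead of 15 for contusion minus normal and 182 instead of 99 for all contused minus all uninjured. Fitting only the compared groups, which leaves fewer arrays to estimate the spread, gave 0 for laminectomy minus normal, for contusion against either uninjured group and for clenbuterol minus contusion. Array weights gave 2 for X-ray minus contusion and 29 for contusion minus normal. The logarithm of signal plus 32 gave 9, 0, 0, 23 and 172 for laminectomy minus normal, contusion minus laminectomy, clenbuterol minus contusion, contusion minus normal and all contused minus all uninjured, and 1 for clenbuterol minus tempol. The spike covariate gave 14 for laminectomy minus normal, 2 for clenbuterol minus contusion, 30 for contusion minus normal and 1 each for clenbuterol minus tempol and clenbuterol minus X-ray. Without laminectomy 2 and normal 1, laminectomy minus normal gave 4 and contusion minus laminectomy 0. With normal cord as its reference the contusion gave 15 and with the mean of both uninjured groups 6. Of the 29 list calls 9 were left with an estimated correlation, a stricter test for lists whose genes vary together. Where neither fewer probe sets nor fewer arrays explains a change, the cause was not tested.

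Leaving out single arrays gave from 1 to 5 probe sets for laminectomy minus normal, 1 to 3 for contusion minus laminectomy, 4 to 16 for contusion minus normal, 59 to 97 for all contused minus all uninjured, 0 to 3 for clenbuterol minus contusion, 0 to 5 for clenbuterol minus tempol, 0 to 2 for clenbuterol minus X-ray and 0 to 3 for X-ray minus tempol. For X-ray, tempol, BSO and tempol plus BSO against contusion, for tempol plus BSO against either agent and for the F test the range was 0 to 1, for the interaction 0 to 0, and the list calls ran from 21 to 31. Of the 134 named gene values that had not passed, 42 moved by a factor over 3 to 2 or changed sign in at least 1 leave-one-out fit, and 21 of the 100 with a size of at least 1 did. The values counted as reversed were these, and smaller changes of sign are not listed. Ugt8 in clenbuterol minus contusion was −0.29 with the mean of its probe sets against 1.27, Klf9 in clenbuterol minus tempol −0.036 with that mean against 1.00, Ccl2 in clenbuterol minus contusion 0.68 without clenbuterol 2 and −1.24 without clenbuterol 1 against −0.28, and Gclm in tempol plus BSO minus contusion 0.41 without tempol plus BSO 1 and −0.76 without tempol plus BSO 2 against −0.27. The cause of these was not tested beyond the disagreement of the probe sets.

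Taking the replicate numbers as a replicate block gave 3 probe sets for laminectomy minus normal, 1 each for contusion minus laminectomy and clenbuterol minus contusion, 10 for contusion minus normal and 71 for all contused minus all uninjured. The numbers do not pair samples across groups, since only 5 of 22 arrays matched best with an array of their own number.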

Other observations

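Clenbuterol, X-ray and tempol were given at the same time after the injury, and their direct comparison, chosen after the data were seen, leaves out the contusion arrays. Against tempol, clenbuterol left the glucocorticoid-responsive genes higher (median 1.03, 13 of 16, adjusted p = 4.10e-05, adjusted p = 0.0123 with an estimated correlation), with Per1 at 1.97 ± 0.62 (3.02 without clenbuterol 1, 0.91 without clenbuterol 2), Dusp1 at 1.33 ± 0.47, the leucine zipper gene Tsc22d3 at 1.16 ± 0.43 and Klf9 at 1.00 ± 0.40, where the mean of all Klf9 probe sets was −0.036. All 10 pericyte and smooth muscle markers were lower (median −0.99, adjusted p = 0.000996, adjusted p = 0.0211 with an estimated correlation), among them the contractile actin gene Acta2 (−0.96 ± 0.44), the muscle filament gene Des (−1.75 ± 0.83) and the peptidase gene Anpep (−1.42 ± 0.59). Oligodendrocyte and myelin genes (0.61, adjusted p = 4.10e-05, adjusted p = 0.218 with an estimated correlation) such as Ugt8 (1.59 ± 0.40) and Mobp (1.35 ± 0.41), and astrocyte markers (0.68, adjusted p = 0.000586, adjusted p = 0.225 with an estimated correlation) such as Aqp4 (1.58 ± 0.49), were higher. Cholesterol synthesis (0.58, adjusted p = 0.0172, adjusted p = 0.365 with an estimated correlation) failed without clenbuterol 2 (0.193) or tempol 2 (0.35, adjusted p = 0.146), with the mean of all probe sets of a gene (0.0849) and with replicate numbers as blocks (0.0561). Interferon-stimulated genes (0.52, adjusted p = 0.0447, adjusted p = 0.218 with an estimated correlation) failed without clenbuterol 2 (0.623), tempol 1 (0.32, adjusted p = 0.108), tempol 2 (0.114) or tempol 3 (0.0549), with the mean of all probe sets of a gene (0.0525) and with quantile normalization (0.0551). By limma 0 probe sets passed with 2029 at unadjusted p under 0.05, Carm1 came closest (−3.28 ± 0.52, adjusted p = 0.121), and the count was 2, 5 and 1 without clenbuterol 1, clenbuterol 2 and tempol 2.

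X-ray also left astrocyte markers (median 0.62, 13 of 14 higher, adjusted p = 0.00119, adjusted p = 0.205 with an estimated correlation) and myelin genes (0.46, 17 of 18, adjusted p = 0.00774, adjusted p = 0.210 with an estimated correlation) higher than tempol did, with S100b at 1.35 ± 0.39, Aqp4 at 1.29 ± 0.44, Mog at 0.90 ± 0.36 and Mobp at 0.85 ± 0.37. The myelin genes failed without X-ray 1 (0.32, adjusted p = 0.0670) and stood at 0.28 without tempol 2. Matrix genes (0.50, adjusted p = 0.0244, adjusted p = 0.101 with an estimated correlation) failed without X-ray 1 (0.0670) or tempol 3 (0.0853). Cytokines and chemokines such as Ccl7 (1.83 ± 0.48) and the interleukin receptor blocker gene Il1rn (1.13 ± 0.49) were higher (0.56, adjusted p = 0.0292, adjusted p = 0.101 with an estimated correlation), and failed without X-ray 1 (0.0670), tempol 1 (0.0999) or tempol 3 (0.0748). The p53 target Ccng1 was 2.20 ± 0.54 higher (adjusted p = 0.502), with the p53 list at 0.41 (adjusted p = 0.0843). By limma 0 probe sets passed with 2007 at unadjusted p under 0.05, Cdyl2 came closest (−2.77 ± 0.45, adjusted p = 0.235), and 3 passed without tempol 2. Against X-ray, clenbuterol left macrophage markers lower (median −0.87, 13 of 15, adjusted p = 9.44e-05, adjusted p = 0.0171 with an estimated correlation), with Spp1 at −1.54 ± 0.46, Gpnmb at −1.49 ± 0.54 and Lyz2 at −1.05 ± 0.41, though not without clenbuterol 2 (−0.39, adjusted p = 0.0681). Glucocorticoid-responsive genes such as Klf9 (1.37 ± 0.40) and Per1 (1.93 ± 0.62, 2.99 without clenbuterol 1, 0.88 without clenbuterol 2) were higher (0.45, 14 of 16, adjusted p = 0.000458, adjusted p = 0.0171 with an estimated correlation), with 0.74 without clenbuterol 2, and failed without clenbuterol 1 (0.18, adjusted p = 0.179). By limma 0 probe sets passed with 1190 at unadjusted p under 0.05, and 2 passed without clenbuterol 1 or without clenbuterol 2. The second principal component (7.98% of the variance) set the clenbuterol and X-ray arrays (34.87 to 53.01) apart from the other contused arrays (−22.91 to 7.10). The uninjured arrays lay at −39.46 to −16.36. The upper quartile of the signal was also lower in the clenbuterol and X-ray arrays (321.9 to 329.5) than in the other contused arrays (332.1 to 341.9). Whether these 2 groups share a difference in array processing was not tested.

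The astrocyte reaction to laminectomy alone may be a true response to the surgery, and both technical tests of it were chosen only after the result was seen. Without the arrays that stand apart, laminectomy 2 and normal 1, the reactive astrocyte median was 1.29 (adjusted p = 1.12e-10) against 1.16, which argues against those arrays as the cause. With the spike covariate, a measure of labelling and hybridization strength, it was 1.18 (adjusted p = 3.35e-11), which argues against that cause too. Neither test bears on a separate processing of the normal arrays, which would enter every comparison with normal cord. Whether they were processed with the others is not given in the sources used here. On the second principal component they lay at −39.46 to −31.09, the laminectomy arrays at −20.67 to −16.36. Surgery or separate processing would give this. Regrouping the 6 arrays tests chance, and its 10 splits are too few for a share under 0.05. The 8 lists called were reached in 1 of 10 splits, the real one, with 5 as the highest other. The 2 probe sets were reached in 3 of 10, the highest being 10 for laminectomy 1, normal 2 and normal 3 against the rest. The other 3 splits that put laminectomy 2 and normal 1 on the same side gave 0. What gave the 10 probe sets was not tested.

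The clenbuterol pattern may be a damped macrophage response with glucocorticoid-like signalling, and all tests of it here were chosen only after the result was seen. Against the mean of tempol, BSO and tempol plus BSO the glucocorticoid-responsive genes were still higher (median 0.95, adjusted p = 3.68e-06, adjusted p = 0.00427 with an estimated correlation). This argues against chance values of the contusion arrays as the cause. It uses the same clenbuterol arrays, so chance values of those were not tested. Against X-ray, which that mean leaves out, the median was 0.45, and 0.18 without clenbuterol 1. On the second principal component and in the upper quartile of the signal, clenbuterol lay with X-ray and apart from the groups of that mean. A processing difference shared by clenbuterol and X-ray could thus add to the larger gap, and this was not tested. For the macrophage markers the same reference gave −0.52 instead of −0.94 (adjusted p = 0.0354). With an estimated correlation that call did not hold (adjusted p = 0.20), so by this reference a true decrease and chance values of the contusion arrays cannot be told apart. Against X-ray, a comparison without contusion arrays, the macrophage markers were lower as well (−0.87, adjusted p = 9.44e-05, adjusted p = 0.0171 with an estimated correlation). That median was −0.39 without clenbuterol 2, which bears on chance values of the clenbuterol arrays. Against tempol, also without contusion arrays, the macrophage markers were not called. Their mean relative to normal cord was 0.79 after clenbuterol, 1.19 after tempol and 1.52 after X-ray. Less lesioned tissue in the clenbuterol samples cannot be told apart from a true decrease either, since of the probe sets found to respond to injury in the other 18 arrays, the 45 that rose outside the macrophage list had a median of −0.00398 (−0.34 to 0.71 with single arrays left out), while the 13 that fell had 0.58 (0.58 to 0.92), and only the second is what less lesioned tissue would give. No corticosterone measurement was used here, so a stress hormone response of the animals to the drug stays as open as a direct action on the cord.

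The higher neuron markers after tempol may rest on the contusion arrays, by a test chosen only after the result was seen. Against the mean of clenbuterol, X-ray and BSO the neuron median was 0.11 (adjusted p = 0.260) instead of 0.53. Chance values of the contusion arrays would give this outcome. A rise of neuron markers in those treated groups would give it as well. Their mean scores were −0.73, −0.84 and −0.76 against −1.09 in contused cord, so the test cannot tell these apart. All 5 treated groups lay above contusion (medians 0.42 to 0.61). In simulations of the mean list score where only chance and the shared arrays acted, all 5 lay above contusion in 19.4% of 100000. Only the side was counted there, so whether chance would give gaps as large as the observed ones was not tested. A protection of neurons by tempol is therefore not shown by these arrays.

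Regrouping was also run for other comparisons; these tests were written down before their results were known, although the comparisons of all contused arrays and of X-ray with tempol had been chosen only after the data were seen. Among 100 drawn splits of the 22 arrays into 16 and 6, fitted with a pair of group means, only 1, the real one, gave as many as 123 probe sets, and the highest other gave 8. For tempol plus BSO against tempol (real 0, highest other 0), against BSO (0 and 2) and X-ray against tempol (0 and 1) no probe set passed, so 10 of 10 splits reach the real count by construction and this says nothing about chance. The 4 lists of X-ray against tempol were reached in 1 of 10 splits with 3 as the highest other, with splits too few for a share under 0.05.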
